A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

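The series holds 9 one-colour Affymetrix Yeast S98 (YG-S98) arrays of total RNA, with 3 arrays each of control BY4743, dried BY4743 and commercial dry active yeast. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, complementary RNA was hybridised, the images were read with the manufacturer's expression software, and probe set signals went through a signed rank test and a mixed model in 2 steps; the software version is not given in the sources used here. The deposited values are 1 intensity per probe set and array on a linear scale, with no log and no centring per probe set. The mean of each array after trimming 2% at each end lay between 500.2 and 500.3, as global scaling to a common target gives, so a scaling was applied; whether a mixed model was applied as well was not tested. Array medians as deposited ran from 159.9 to 194.7. The commercial arrays' descriptions repeat the protocol text of the BY4743 arrays, so the growth and drying of the commercial yeast remain unknown. No hybridisation or scan dates were found, and a hybridisation batch that coincides with a group cannot be told apart from that group.

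Signals below a floor of 1 were raised to 1 and log2 was taken. The log2 medians of the arrays spanned 0.284, above the tolerance of 0.1 set beforehand, so arrays were quantile normalized with limma 3.58.1 in R 4.3.3; signals printed in the text are means of these normalized values on the linear scale. The 60 control probe sets were left out of the tests and 9275 were tested. One mean per group was fitted to the 9 arrays with lmFit, contrasts were tested two-sided with eBayes (6 residual and 1.64 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The comparisons were dried against control BY4743, commercial against dried BY4743, and commercial against control BY4743. Quantile normalization gives every array the same distribution, so changes are relative to the middle of all transcripts on an array and a change of the whole messenger pool would not be seen. Under the main setting the median log2 change of all probe sets was 0.04, 0.00 and -0.01 in the 3 comparisons; it was 0.12, 0.13 and 0.22 with the values as deposited, -0.06, 0.16 and 0.07 with each array centred on its median, and -0.29, -1.10 and -1.43 with arrays scaled to the spike-in controls.

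Background was set, after the data were seen, as the 95th percentile of 28 control probe sets whose targets are absent, per array; it was 32.2 to 59.5 in normalized signal, with a median of 46.0. Where a probe set lay at or under background on all 3 arrays of a group, the fold change is given as a bound: the brighter group's mean log2 signal against the dimmer group's mean of, per array, the higher of background and the probe set's own signal. No fold is given where both groups lay at background. Signals near background scatter in an intensity-dependent way that the array number, not a count of reads, limits.

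Probe sets were named from the platform annotation, updated by gene identifier to the RefSeq table of assembly R64. Exactly 1 gene was named by 6504 probe sets, several by 328 and none by 2503, of which 2443 were tested and are only counted. Probe sets with shared-probe suffixes in their names are called uncertain. No genome build is named for the probes, so no coordinates are given. For gene lists a gene was represented by its probe set with the highest mean signal (5656 genes).

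The 33 gene lists, the design of each test, the rule for named genes and the alternatives were fixed before the data were examined; the background level, the bounds and 3 further settings (floor at background, only probe sets without shared probes, scaling to spike-ins) were chosen afterwards. The lists cover desiccation and stress (trehalose and glycogen, hydrophilins, heat shock, oxidative defence, glycerol), carbon and energy (glycolysis, gluconeogenesis, fatty acid oxidation, TCA cycle, oxidative phosphorylation, mitochondrially encoded genes, hexose transport, maltose and sucrose), growth (cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, proteasome, autophagy, amino acids, ergosterol, purines), cell cycle (histones and replication, cyclins), vitamins, metals, phosphate, cell wall, and strain or cell type (haploid mating, meiosis, stationary phase, BY4743 marker loci, genes of variable copy number). Lists were tested with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 33 lists of a contrast, and again with an estimated correlation and with fry. Named genes are, per contrast, from the 6 highest and 6 lowest log2 changes among probe sets past the threshold that name 1 gene and whose groups do not overlap, up to 4 members per list with the largest change, and the 5 marker loci; not all of them are named, and genes named outside this rule are said to be so. RNA quality was the log2 difference between 3' and 5' control probe sets of ACT1, SPT15 and SRB4, compared with an exact two-sided permutation test, for which 3 against 3 arrays cannot give a p under 0.1.

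The code was tested on simulated data with the spread of the real arrays. With 9275 probe sets it recovered 31.3%, 58.2% and 86.4% of probe sets changed 1.5-fold, 2-fold and 4-fold for dried against control BY4743, with 4.88% false calls. For commercial against dried BY4743 it recovered 31.5%, 60.4% and 84.6%, with 5.62% false, and for commercial against control BY4743 26.9%, 50.7% and 81.8%, with 6.19% false. For dried against control BY4743 only 67, 67 and 66 simulated probe sets were changed at these folds, whereas 69.2% of the real ones were called. With such different shares, these rates test the code and do not describe recovery in the real comparisons. Alternatives were the values as deposited, median centring, leaving out the dimmest 25% of probe sets, an offset of 50 in place of the floor, the replicate number as a block, only the 6 arrays compared, a 2-fold minimum, eBayes with trend and robust options, array weights and each array left out in turn. Figures were drawn with matplotlib 3.10.9.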

Results

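RNA of Saccharomyces cerevisiae was measured on 9 Affymetrix Yeast S98 arrays, in 3 groups of 3 arrays. BY4743 is a diploid laboratory strain of the S288C family in which URA3, LEU2 and HIS3 are disrupted on both chromosome sets. Control BY4743 cells were harvested from growth in rich glucose medium at 30 °C at an A600 of 0.8 and resuspended in diluted medium. Dried BY4743 cells came from such suspensions that had dried for 42 h and then been held at 20% relative humidity for 72 h. The last group was commercial dry active yeast, whose own strain, culture and drying were not given in the sources used here. Each array carried 9335 probe sets, of which 9275 were tested and 60 were control probe sets. Between 72.1% and 81.3% of the probe sets lay above the background of an array. Array profiles correlated across probe sets, which are not independent replicates, at Pearson's r of 0.971 to 0.981 within a group. Between groups r was 0.796 to 0.802 for control and dried BY4743, 0.823 to 0.835 for dried BY4743 and commercial yeast, and 0.764 to 0.779 for control BY4743 and commercial yeast. The number of arrays, 3 per group, limits the precision of every value. Nothing in the labels said whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Values after ± are SD over 3 arrays, and bounds written as "at least" hold against the background of the arrays where a transcript was not measured. A p-value printed beside such a bound tests the fitted change, which counts signals under background, and not the bound.

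The genotype of BY4743 allowed a check of the labels. URA3, an enzyme of uracil synthesis, lay at background in control BY4743 (signal 2.80 ± 0.398, n = 3) and in dried BY4743 (1 ± 0, the floor), and read 365 ± 36.3 in commercial yeast. That was at least 7.16-fold higher than in dried BY4743 (limma, Benjamini-Hochberg adjusted p = 4.77e-09 for the fitted change) and at least 8.86-fold higher than in the control (adjusted p = 8.76e-09 for the fitted change). LEU2, of leucine synthesis, read 84.5 ± 11.4 in the control, was at background in dried BY4743, and read 382 ± 54.3 in commercial yeast. Its rise was at least 7.49-fold over dried BY4743 and 2.18 on the log2 scale (SE 0.39) over the control. HIS3 read 1026 ± 114, 129 ± 15.0 and 365 ± 40.2 in control, dried and commercial yeast. The BY4743 deletion removes only part of this gene and the probes may lie outside it, so HIS3 checked nothing. Of the loci deleted on 1 chromosome set in BY4743, LYS2 read 500 ± 132, 152 ± 32.2 and 309 ± 15.6, and MET17, also called MET15, read 1829 ± 44.2, 566 ± 32.0 and 2944 ± 300. The URA3 levels matched the labels, but the LEU2 signal of the control lay above background, against the genotype. A LEU2 probe set with shared probes, looked at after the values were seen, lay at background in control (16.8 ± 13.4) and dried BY4743 (15.2 ± 11.1) and read 253 ± 103 in commercial yeast.

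**Figure D1:**
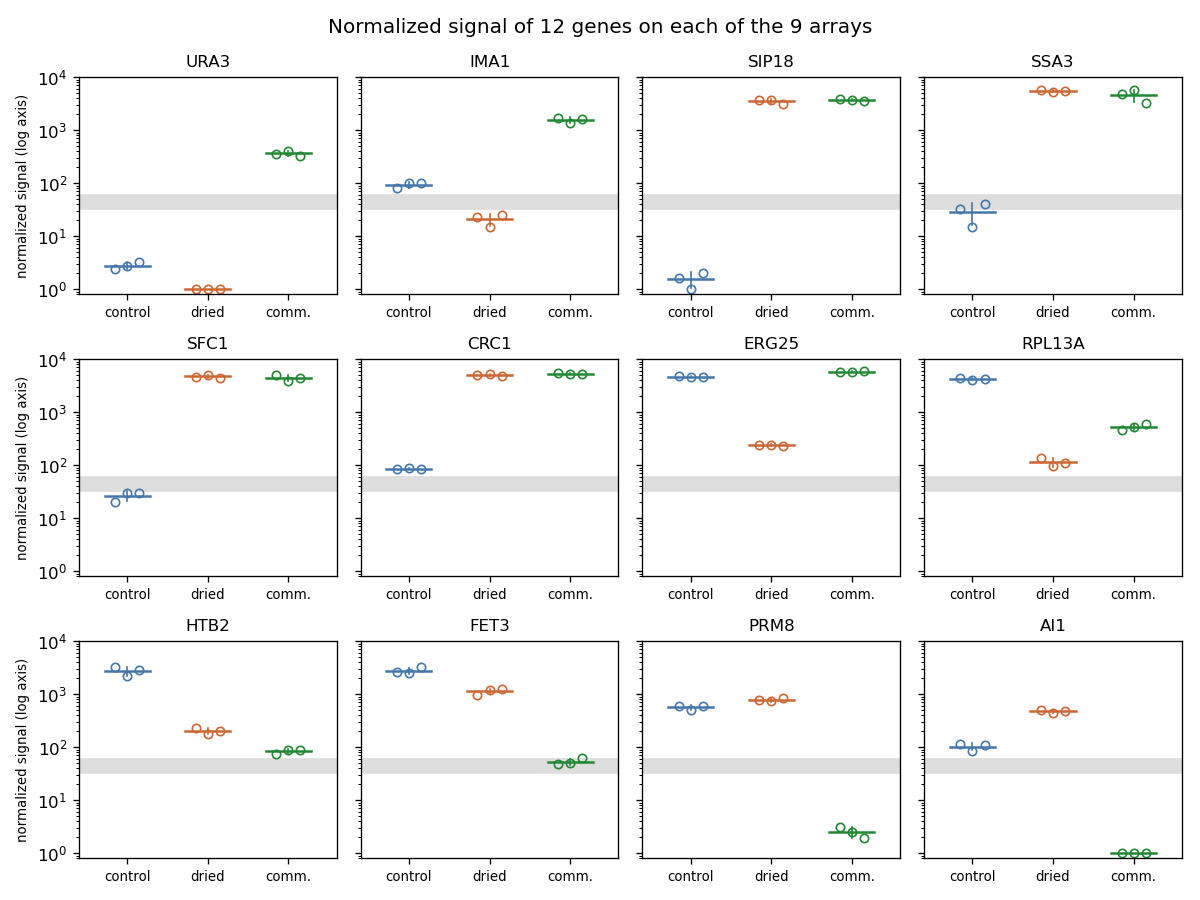
Normalized signal (log axis) of 12 genes on each of the 9 arrays, by group (control BY4743, dried BY4743, commercial yeast); open points are arrays, horizontal lines group means and vertical lines the SD, drawn down to no less than the axis minimum. The grey band spans the background of the arrays, 32.2 to 59.5; URA3 rose above it only on the commercial arrays, and SIP18 only on the dried BY4743 and commercial arrays.

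The first comparison set dried BY4743 against the control and asks how the transcript pool of a laboratory strain differed after drying. Drying took 42 h and the hold at 20% relative humidity 72 h, and no undried group was held for as long. Effects of drying therefore cannot be told apart from those of the time that passed, including any change in nutrients. Dried cells carried high levels of transcripts for fat breakdown, autophagy and stationary phase, and low levels of transcripts for making cytosolic ribosomes, amino acids, purines and sterols. The list of hydrophilins and desiccation genes did not pass, though single members rose far. SIP18, a hydrophilin made under desiccation, rose from background (1.56 ± 0.521, n = 3) to 3502 ± 329, at least 85.2-fold. SSA3, a stress-induced chaperone, rose from background to 5448 ± 216, at least 133-fold, and SFC1, a mitochondrial succinate-fumarate carrier, rose to 4720 ± 283, at least 115-fold. RPL13A, of the large ribosomal subunit, fell from 4260 ± 183 to 115 ± 21.8, a log2 change of -5.22 (SE 0.15).

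In all, 3358 of 9275 probe sets were higher and 3063 lower in dried BY4743, 69.2% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 2019 and 2032 of these changed at least 2-fold. They named 2345 genes with a higher and 2190 with a lower probe set. On 74.6% of the probe sets the arrays of the groups did not overlap, where chance gives 10%. The median SE of the called changes was 0.134 on the log2 scale, and 405 called probe sets lay at background in both groups. With arrays scaled to the spike-in controls in place of quantile normalization, 1767 were higher and 2989 lower, so higher calls made up 37.2% in place of 52.3%. By fitted change, which counts unmeasured values under background, the highest also included YDR524C-B, a small protein gene, from the floor to 4342 ± 51.9, at least 106-fold, and YKL107W, from the floor to 2025 ± 123, at least 49.3-fold. FDH1, formate dehydrogenase, rose at least 122-fold by a probe set that shares probes with other sequences, so its identity is uncertain. The lowest by fitted change included FKS1, a cell wall glucan synthase, from 533 ± 38.2 to background by 1 of its probe sets (at least 10.5-fold), PAN5, of pantothenate synthesis, at least 15.8-fold, and HEM13, of heme synthesis, at least 11.1-fold. By its brightest probe set, looked at after the values were seen, FKS1 fell only from 5155 ± 236 to 669 ± 17.2, a log2 change of -2.95 (SE 0.12), so the bound belongs to the dim probe set. These bounds are smaller than the measured falls of SUN4 and ASN1 given below.

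Some lists of carbon use, recycling and arrest were higher. Of 19 genes of gluconeogenesis, the glyoxylate cycle and non-sugar carbon uptake, 15 were higher and 2 lower, with a median log2 change of 3.33 (camera adjusted p = 7.95e-05; adjusted p = 0.0981 with an estimated correlation). CIT3, a mitochondrial citrate synthase, rose at least 73.8-fold and ADY2, an acetate transporter, by 5.62 on the log2 scale. Of 28 genes of fatty acid oxidation and peroxisomes, 27 were higher and 1 lower (median 2.72, adjusted p = 4.91e-08), among them CRC1, a carnitine carrier, by 5.88 (SE 0.07), POX1, acyl-CoA oxidase, by 5.72 (SE 0.13) and PXA1, a peroxisomal transporter, by 5.16 (SE 0.11). Stationary phase markers rose in 19 of 20 cases and fell in 1 (median 2.80, adjusted p = 1.34e-06). Autophagy genes rose in 24 of 27 cases and fell in 2 (median 1.40, adjusted p = 1.98e-05), with ATG11 at 4.21, ATG1 at 2.84 and ATG14 at 2.74. Meiosis and sporulation markers were higher in 17 of 29 cases and lower in 2 (median 0.90, and 0.39 with the offset of 50; adjusted p = 0.0328; adjusted p = 0.0981 with an estimated correlation), with DMC1, a meiotic recombinase, at 3.41. That list's median was 0 and its call was lost (adjusted p = 0.198) with the floor raised to the background level, a setting chosen after the data were seen.

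Several lists of growth genes were lower. Of 81 measured cytosolic ribosomal protein genes, 72 were lower and 2 higher, with a median of -2.86 (adjusted p = 1.62e-14). RPS26B fell by 5.27 on the log2 scale (SE 0.31). RPP0, also in that list, rose by 5.48, but its control arrays scattered widely (152 ± 131) and the SE was 1.89, and an effect of saturation was not tested. Of 70 ribosome biogenesis genes 55 were lower and 6 higher (median -1.35, adjusted p = 4.58e-08), with the nucleolar proteins NOP56 at -4.60, NOP1 at -4.15 and GAR1 at -4.09. Genes of RNA polymerases I and III were lower in 15 of 24 cases and higher in 6 (median -0.52, adjusted p = 0.0328; adjusted p = 0.0981 with an estimated correlation). RPA49, a subunit of RNA polymerase I, changed by -3.57, and RRN3, which recruits that polymerase, by 3.55. Mitochondrial ribosomal protein genes were lower in 34 of 56 cases and higher in 8 (median -0.60, adjusted p = 0.00377; adjusted p = 0.0829 with an estimated correlation), with MRPS8 at least 5.16-fold lower, MRPL32 at -2.14 and MRPL28 at 1.94. Amino acid synthesis genes fell in 48 of 58 cases and rose in 5 (median -1.90, adjusted p = 3.04e-08), led by ASN1, asparagine synthetase, at -5.51 (SE 0.20) and HIS1, of histidine synthesis, at -5.50 (SE 0.18). Purine synthesis genes fell in 16 of 17 cases, with 0 higher (median -2.61, and -1.66 without shared probes; adjusted p = 3.37e-06), including IMD4, IMP dehydrogenase, at -4.36 and GUA1, GMP synthase, at -4.14. Ergosterol synthesis genes fell in 19 of 23 cases and rose in 2 (median -1.97, adjusted p = 7.46e-06), including ERG4 at -5.30, ERG6 at -4.66 and MVD1 at -4.33.

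The lists of cyclins and of the cell wall were lower only with the preset correlation, and that of histones and replication did not pass. Of 18 cyclin and mitosis genes 12 were lower and 2 higher (median -1.06, adjusted p = 0.0438; adjusted p = 0.107 with an estimated correlation). The G1 cyclin CLN2 fell to background (at least 4.33-fold) and CLN3 changed by -2.94. The cyclin call was lost without the dimmest 25% of probe sets (median -0.75, adjusted p = 0.269), without shared probes (0.0716) and without control replicate 1 or 2 (0.0542 and 0.0517). Of 30 cell wall genes 20 were lower and 5 higher (median -1.15, adjusted p = 0.0055; adjusted p = 0.147 with an estimated correlation), including SUN4 at -5.56, GAS1, a glucan-remodelling enzyme, at -3.89 and UTR2, which links chitin to glucan, at least 24.6-fold lower. The 5 BY4743 marker loci were all lower (median -1.69, adjusted p = 0.0281; adjusted p = 0.101 with an estimated correlation), though URA3 lay at background in both groups and has no fold change.

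The other 18 lists did not pass in this comparison. They gave, as higher and lower of those measured, 8 and 7 of 19 trehalose and glycogen genes (adjusted p = 0.99), 6 and 5 of 14 hydrophilins and desiccation genes (0.689), 9 and 8 of 25 heat shock genes (0.996), 9 and 9 of 22 oxidative defence genes (0.865). There were 3 and 7 of 13 glycerol and osmotic genes (0.415). Single members moved far in opposite directions: GRE1, a hydrophilin, rose by 6.05 and HSP26, a small heat shock protein, by 3.27, while the chaperones SSA2 and HSP10 changed by -2.37 and -2.10. ATH1, acid trehalase, rose by 3.37 and GPH1, glycogen phosphorylase, changed by -2.24. CTA1, peroxisomal catalase, rose by 5.77. Glycolysis and fermentation gave 6 and 9 of 21 (0.451), the TCA cycle 7 and 8 of 18 (0.99), oxidative phosphorylation 20 and 10 of 35 (0.208). Mitochondrially encoded genes gave 5 and 0 of 8 (0.22), hexose transport 4 and 8 of 15 (0.502), and maltose and sucrose use 1 and 5 of 8 (0.707). Among these HXK2, the main hexokinase on glucose, changed by -4.56, HXT3, a hexose transporter, by -4.62, HXT1 by -3.61 and HXT5, a transporter of slow-growing cells, by 4.15. HXT4 was at least 35.6-fold lower and ATP6, a mitochondrially encoded ATP synthase subunit, rose by 4.06. The proteasome gave 14 and 11 of 34 (0.865), histones and replication 8 and 7 of 25 (0.833), thiamine, biotin and pyridoxine 7 and 6 of 16 (0.865), iron, copper and zinc 12 and 9 of 25 (0.865) and phosphate response 4 and 9 of 14 (0.188). Haploid mating markers gave 5 and 5 of 21 (0.99) and genes whose copy number varies between strains 7 and 7 of 19 (0.757). The median, mean and test differed in sign for the heat shock, glycolysis, TCA, iron and haploid lists.

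Of the 15 lists past the threshold in this comparison, 8 passed with an estimated correlation. Without the dimmest 25% of probe sets the meiosis (adjusted p = 0.0648) and marker (0.0637) calls were lost, and with spike-in scaling those of mitochondrial ribosomal proteins and RNA polymerases I and III (0.106 each, with the median of the polymerases at -0.88). The marker call was also lost with the offset of 50 (camera adjusted p = 0.0673) and with the floor raised to background (0.0925). Adjusted over the list alone, 27 of 33 lists gave the same counts as over all probe sets, and the 6 others differed by at most 2 genes. RNA quality differed between the groups: the difference between the 3' and 5' control probe sets of ACT1, actin, was -0.395 ± 0.274 (log2, n = 3) in the control and 1.40 ± 0.173 in dried BY4743, higher by 1.80 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The same difference was 0.316 higher for SPT15 (exact p = 0.1) and 0.274 higher for SRB4 (exact p = 0.2).

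**Figure D2:**
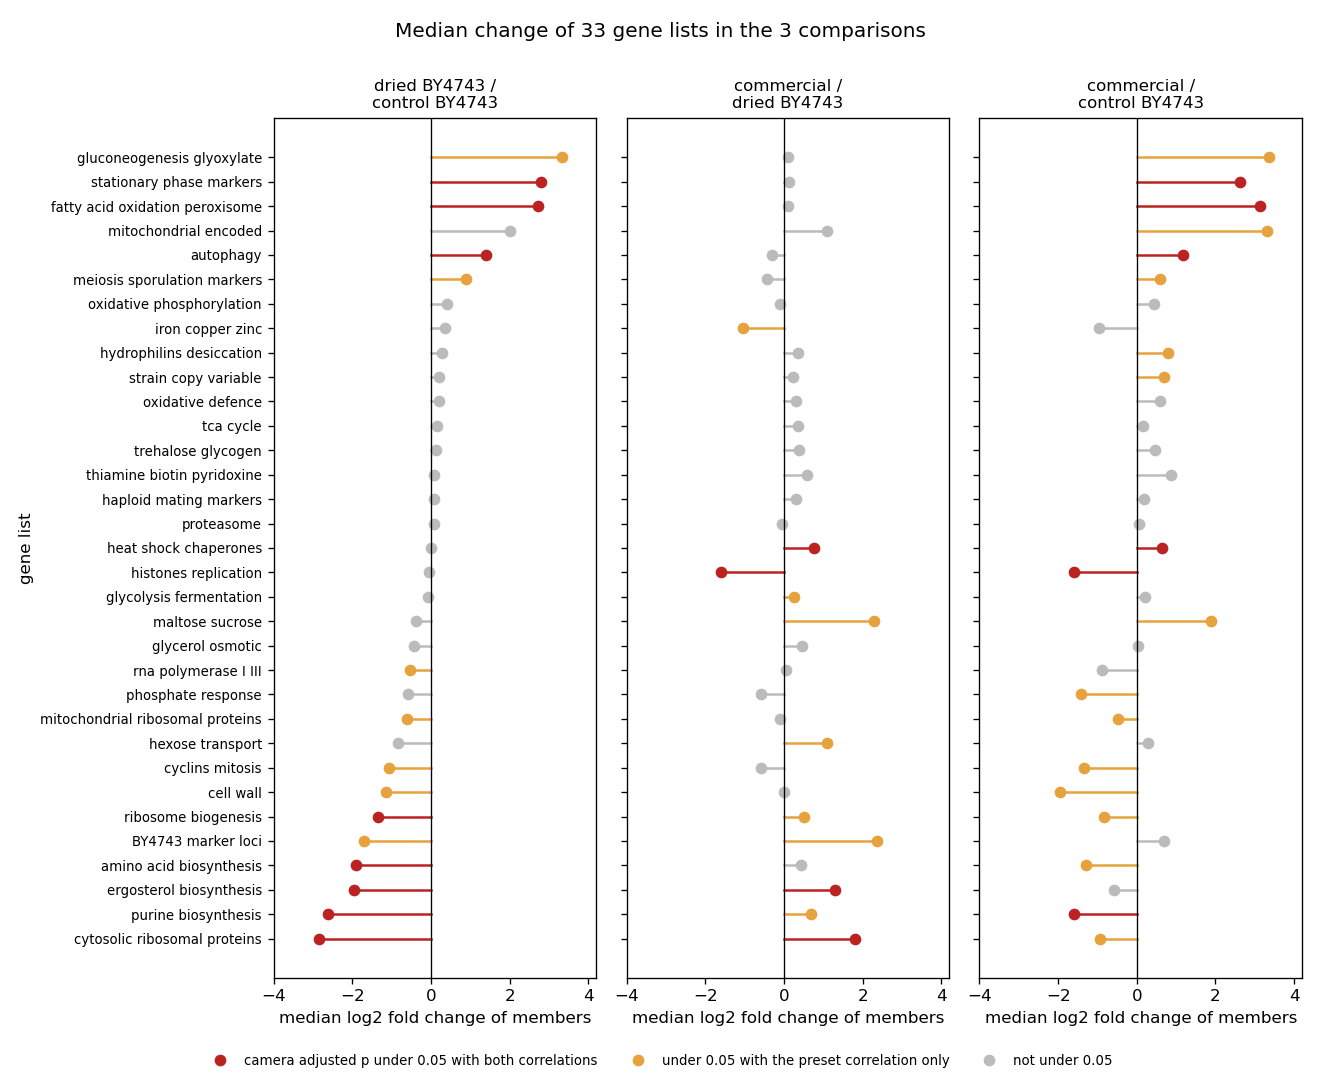
Median log2 fold change of the measured members of 33 gene lists in the 3 comparisons, sorted by the first panel; red marks lists past a camera adjusted p of 0.05 with the preset and the estimated correlation, orange the preset correlation alone, grey neither. Cytosolic ribosomal proteins had a median of -2.86 in dried BY4743 against the control and 1.80 in commercial against dried BY4743; with arrays scaled to the spike-in controls the medians of 0 of 15, 4 of 11 and 5 of 19 called lists changed sign, from left to right.

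The second comparison set commercial dry yeast against dried BY4743, the pair the series was named for. Strain, culture and drying differ together. A low reading in commercial yeast may also come from sequence that its strain lacks or carries in diverged form, which stays open. Commercial yeast carried more transcript for sterol synthesis, cytosolic ribosomal proteins and heat shock proteins, and less for histones and DNA replication. With spike-in scaling the rises shrank to medians of 0.10 for sterol synthesis and 0.41 for cytosolic ribosomal proteins, and the median of heat shock was -0.51. Lists of sugar use were higher and the list of iron, copper and zinc genes lower with the preset correlation alone (adjusted p = 0.311 for maltose and sucrose, 0.179 for hexose transport, 0.389 for glycolysis and 0.311 for iron, copper and zinc with an estimated correlation). SUC2, the secreted invertase that splits sucrose, was, by its probe set without shared probes, at the floor in both BY4743 groups and read 1983 ± 76.4 in commercial yeast (n = 3), at least 39.1-fold higher than in dried BY4743. Its 2 probe sets with shared probes, looked at after the values were seen, read 541 ± 38.2 and 681 ± 33.9 in the control and 112 ± 23.9 and 130 ± 14.9 in dried BY4743, so absence of SUC2 transcript from BY4743 was not shown. ERG25, a sterol methyl oxidase, read 240 ± 8.74 in dried BY4743 and 5807 ± 69.4 in commercial yeast, a rise of 4.60 on the log2 scale (SE 0.07). FET3, the copper oxidase of high-affinity iron uptake, read 1134 ± 141 and 53.5 ± 7.61, a log2 change of -4.41 (SE 0.15).

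Of 9275 probe sets 3067 were higher and 3103 lower in commercial yeast, 66.5% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05), with 1786 and 1750 at least 2-fold. They named 1870 genes with a higher and 2212 with a lower probe set, and 454 called probe sets lay at background in both groups. On 72.8% of the probe sets the arrays did not overlap, against 10% by chance, and the median SE of the called changes was 0.140 on the log2 scale. With arrays scaled to the spike-in controls 819 were higher and 5387 lower, so higher calls made up 13.2% in place of 49.7%. CCW12, a cell wall mannoprotein, rose from the floor to 4101 ± 209, at least 80.7-fold (it read 131 ± 113 in the control). Whether signals near saturation made abundant transcripts such as CCW12 read low was not tested, so this bound is uncertain. Lower in commercial yeast and at background there were PRM8, a membrane protein gene, at least 21.2-fold, AI1, an intron-encoded reading frame of the mitochondrial COX1 gene, at least 12.7-fold, PDS5, a sister chromatid cohesion factor, at least 6.58-fold, and RCK2, a stress-activated kinase, at least 4.64-fold. By probe sets that share probes with other sequences, and so uncertain, RDN37-1 and RDN25-1, of the ribosomal RNA repeat, were at least 115-fold lower and changed by -7.50 on the log2 scale. The 25S control probe sets disagreed: a read 2369 in dried BY4743 and 3349 in commercial yeast, but e read 2321 and 52.4. On 1 dried array e read only 139. Probe sets b, c and d, dim in both groups, were lower in commercial yeast. A fall of the ribosomal RNA itself was therefore not shown.

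Maltose and sucrose genes were higher in 6 of 8 cases and lower in 2 (median 2.29, and 1.36 with spike-in scaling; adjusted p = 0.0434; adjusted p = 0.311 with an estimated correlation): IMA1, isomaltase, read 1569 ± 175 and was at least 30.8-fold higher, and MAL11, a maltose transporter, rose by 3.78 (SE 0.16). Hexose transport genes were higher in 10 of 15 cases and lower in 2 (median 1.10, but 0.05 with spike-in scaling; adjusted p = 0.0475; adjusted p = 0.179 with an estimated correlation), with HXT4 at least 5.64-fold and HXT8 at least 2.80-fold higher. Glycolysis and fermentation genes were higher in 9 of 21 cases and lower in 1 (median 0.26, 0.56 as deposited and 0.59 with median centring, but -0.67 with spike-in scaling; adjusted p = 0.0462; adjusted p = 0.389 with an estimated correlation), including PDC6, a minor pyruvate decarboxylase, at 4.37.

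Cytosolic ribosomal protein genes were higher in 73 of 81 cases and lower in 2 (median 1.80, and 0.41 with spike-in scaling; adjusted p = 9e-17), including RPS14B at 3.41 (SE 0.14) and RPL21A at 3.06 (SE 0.45). Ribosome biogenesis genes were higher in 46 of 70 cases and lower in 10 (median 0.51, but -0.73 with spike-in scaling; adjusted p = 0.000107; adjusted p = 0.11 with an estimated correlation), with UTP15 at least 4.91-fold higher, GAR1 at 2.46 and NOP56 at 2.20. Ergosterol genes were higher in 18 of 23 cases and lower in 2 (median 1.31, but 0.10 with spike-in scaling; adjusted p = 1.18e-05), with ERG5 at 4.50 (SE 0.17) and ERG6 at 3.55 (SE 0.18). Purine synthesis genes were higher in 11 of 17 cases and lower in 3 (median 0.69, but -0.71 with spike-in scaling; adjusted p = 0.0434; adjusted p = 0.179 with an estimated correlation), including GUA1 at 1.53. The purine call was lost with the values as deposited (adjusted p = 0.0553), with median centring (0.0681), without the dimmest 25% of probe sets (0.0503) and without shared probes (0.0786). Heat shock genes were higher in 16 of 25 cases and lower in 1 (median 0.76, but -0.51 with spike-in scaling; adjusted p = 0.000736), with SSA4 at 3.30, HSP10 at 2.69 and SSA2 at 2.19 higher and HSP150, a secreted cell wall protein, at -3.01. The 5 BY4743 marker loci were all higher (median 2.37, and 1.10 with spike-in scaling; adjusted p = 0.00433; adjusted p = 0.0927 with an estimated correlation).

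Histone and DNA replication genes were lower in 20 of 25 cases and higher in 2 (median -1.60, and -2.76 with spike-in scaling; adjusted p = 9.71e-05). The helicase subunits MCM6 and MCM7 were at least 3.63-fold lower and changed by -2.48. RFA3, of the single-strand binding complex, changed by -4.51 (SE 0.22) and POL1, DNA polymerase alpha, by -2.36 (SE 0.27). Iron, copper and zinc genes were lower in 15 of 25 cases and higher in 4 (median -1.03, -0.53 with the floor raised to background, -0.51 with the offset of 50 and -2.22 with spike-in scaling; adjusted p = 0.0475; adjusted p = 0.311 with an estimated correlation), including SIT1, a siderophore transporter, at -3.55 and FIT2, a cell wall siderophore protein, at -3.39.

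The other 22 lists did not pass in this comparison. Higher and lower members numbered 11 and 5 of 19 for trehalose and glycogen (adjusted p = 0.129), 7 and 1 of 14 for hydrophilins (0.0536), 10 and 3 of 22 for oxidative defence (0.0717), 7 and 1 of 13 for glycerol and osmotic genes (0.0636), and 5 and 2 of 19 for gluconeogenesis (0.362). They numbered 11 and 7 of 28 for fatty acid oxidation (0.266), 9 and 2 of 18 for the TCA cycle (0.129) and 7 and 14 of 35 for oxidative phosphorylation (0.703). STL1, a glycerol transporter, rose by 3.47 and THI4, of thiamine synthesis, by 4.44. Further counts were 5 and 0 of 8 mitochondrially encoded genes (0.0717), 19 and 19 of 56 mitochondrial ribosomal proteins (0.851), 8 and 5 of 24 for RNA polymerases I and III (0.362), and 10 and 9 of 34 for the proteasome (0.915). There were 2 and 12 of 27 for autophagy (0.0909), 30 and 16 of 58 for amino acid synthesis (0.0536) and 4 and 10 of 18 for cyclins (0.325). Thiamine, biotin and pyridoxine gave 9 and 4 of 16 (0.0636), phosphate response 2 and 7 of 14 (0.161), and cell wall 11 and 11 of 30 (0.851). Haploid mating markers gave 8 and 6 of 21 (0.523), meiosis 7 and 11 of 29 (0.735), stationary phase markers 9 and 4 of 20 (0.37) and genes of variable copy number 9 and 7 of 19 (0.247). In that last list FLO11, a cell surface adhesin, rose by 5.17 (SE 0.15). The median, mean and test differed in sign for the mitochondrial ribosomal protein, proteasome and cell wall lists.

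Of the 11 lists past the threshold in this comparison, 4 passed with an estimated correlation: heat shock, cytosolic ribosomal proteins, ergosterol and histones. Adjusted over the list alone, 28 of 33 lists gave the same counts, and the 5 others differed by at most 1 gene. The hexose list missed the threshold without commercial replicate 1 or 3 (adjusted p = 0.0511 and 0.0563), and the iron list without commercial replicate 3 (adjusted p = 0.0542). Without the dimmest 25% of probe sets the glycolysis (0.0572), hexose (0.0503) and iron (0.0549) calls were lost too. Leaving out shared probes ended the maltose and sucrose (median 1.91, camera adjusted p = 0.06), hexose (0.0792) and iron (0.0558) calls. The replicate block ended those of maltose and sucrose, glycolysis, purines and iron (0.0516 each) and of hexose transport (0.0523). The hydrophilin list, not past the threshold here, passed with the values as deposited (adjusted p = 0.0135), with median centring (0.0188) and without any single dried BY4743 array (0.0477 to 0.0492). As deposited and with median centring, the TCA cycle (camera adjusted p = 0.0412 and 0.0432), mitochondrially encoded (0.0443 and 0.0432) and thiamine (0.0412 and 0.0432) lists passed as well. The 3' minus 5' difference in commercial yeast was 0.418 ± 0.0980 for ACT1 (n = 3), a change of -0.98 from dried BY4743, and higher than there by 0.36 for SPT15 (exact two-sided permutation p = 0.1 for each). The 5' probe set of SRB4 lay at background on all 3 commercial arrays, so its difference was only bounded, at 0.33 or more above dried BY4743.

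**Figure D3:**
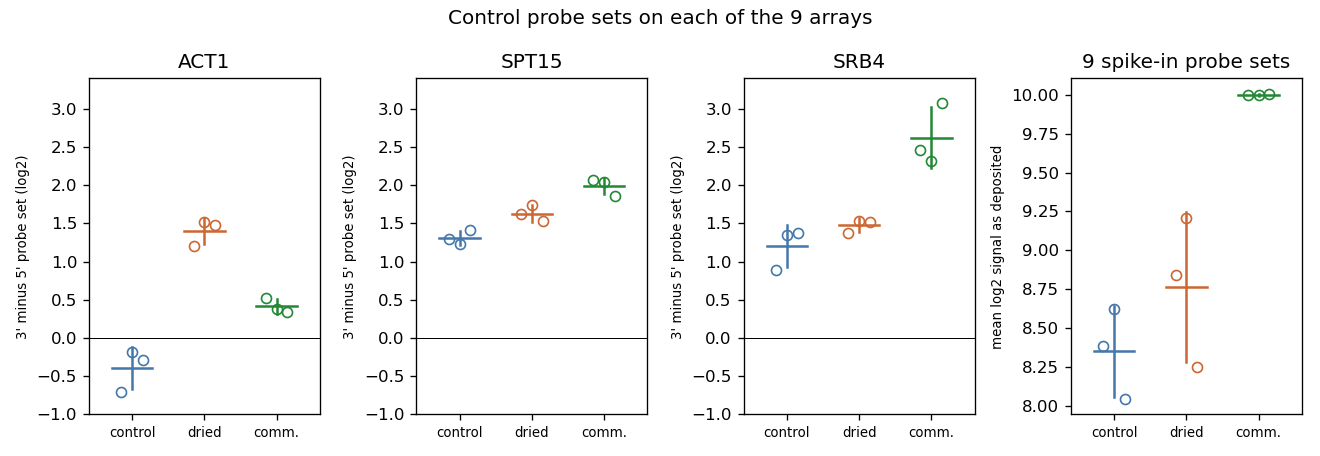
Control probe sets on each of the 9 arrays: the first 3 panels give the 3' minus the 5' probe set of ACT1, SPT15 and SRB4 (log2 of normalized signal), the last panel the mean log2 deposited signal of 9 spike-in probe sets. Points are arrays, horizontal lines group means and vertical lines the SD. The SRB4 points of commercial yeast rest on a 5' probe set at background; ACT1 was highest on the dried BY4743 arrays (1.40 ± 0.173) and the spike-ins were highest on the commercial arrays.

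The third comparison set commercial dry yeast against control BY4743. Here too, sequence that the commercial strain lacks or carries in diverged form stays open as a source of low readings. Transcripts of fat breakdown, stationary phase, autophagy and heat shock were higher in commercial yeast and those of histones, replication and purine synthesis lower, with both correlations, although the medians of autophagy (-0.34) and heat shock (-0.83) were negative with spike-in scaling. The other 13 lists past the threshold lost their calls with an estimated correlation. SIP18 read 3729 ± 187 in commercial yeast (n = 3), at least 90.9-fold above the control, and PDC6 rose from background to 2807 ± 297, at least 68.2-fold. CRC1 rose by 5.96 on the log2 scale (SE 0.07) and ATP6 by 5.60 (SE 0.13). PRY2, a sterol-binding protein gene, fell from 2089 ± 96.0 to background, at least 56.2-fold, and HTB2, histone H2B, fell from 2762 ± 532 to 84.5 ± 9.18, a log2 change of -5.02 (SE 0.17).

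Of 9275 probe sets 3293 were higher and 3434 lower, 72.5% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05), with 2095 and 2237 at least 2-fold. They named 2140 genes with a higher and 2439 with a lower probe set, and 409 called probe sets lay at background in both groups. The arrays did not overlap on 75.5% of the probe sets, against 10% by chance, and the median SE of the called changes was 0.138. With arrays scaled to the spike-in controls 814 were higher and 6070 lower, so higher calls made up 11.8% in place of 49.0%. By fitted change, which counts unmeasured values under background, the highest included YDR524C-B, at least 83.1-fold, SUC2, at least 48.3-fold by the probe set without shared probes (the others read 541 and 681 in the control), and YKL107W, at least 43.8-fold. The lowest by fitted change included BAP3, an amino acid permease, at least 27.9-fold, PAN5 at least 21.5-fold and PRM8 at least 15.1-fold, bounds smaller than the measured falls of ASN1 and PHO3 given below.

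Fatty acid oxidation and peroxisome genes were higher in 27 of 28 cases, with 0 lower (median 3.14, and 1.72 with spike-in scaling; adjusted p = 3.31e-09), including POX1 at 6.06 (SE 0.13). Gluconeogenesis and glyoxylate genes were higher in 15 of 19 cases and lower in 1 (median 3.36, and 1.97 with spike-in scaling; adjusted p = 2.68e-06; adjusted p = 0.0573 with an estimated correlation), with SFC1 at least 108-fold higher, ADY2 at 5.75 (SE 0.09) and JEN1, a lactate transporter, at 5.41 (SE 0.18). Stationary phase markers were higher in 19 of 20 cases, with 0 lower (median 2.64, and 1.13 with spike-in scaling; adjusted p = 5.64e-08). Autophagy genes were higher in 20 of 27 cases and lower in 2 (median 1.18, 0.78 with the offset of 50, but -0.34 with spike-in scaling; adjusted p = 0.000347), with ATG11 at 3.50 and ATG1 at 2.74. Mitochondrially encoded genes were higher in 5 of 8 cases, with 0 lower (median 3.32, 1.58 with the floor raised to background, 1.62 with the offset of 50 and 2.17 with spike-in scaling; adjusted p = 0.0268; adjusted p = 0.0959 with an estimated correlation), including COB at 3.96 and COX3 at 3.77, and COX2 at least 8.73-fold higher. Without the dimmest 25% of probe sets this list missed the threshold (adjusted p = 0.0726).

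Heat shock genes were higher in 18 of 25 cases and lower in 3 (median 0.64, but -0.83 with spike-in scaling; adjusted p = 0.00181), with SSA3 at least 109-fold higher and HSP26 at 3.18. Hydrophilins and desiccation genes were higher in 8 of 14 cases and lower in 1 (median 0.79, but -0.65 with spike-in scaling; adjusted p = 0.0127; adjusted p = 0.0797 with an estimated correlation), with GRE1 at 6.73 (SE 0.18). Maltose and sucrose genes were higher in 7 of 8 cases and lower in 1 (median 1.89, and 0.46 with spike-in scaling; adjusted p = 0.0127; adjusted p = 0.184 with an estimated correlation), with IMA1 at 4.06 and MAL11 at 3.34. Genes of variable copy number were higher in 13 of 19 cases and lower in 6 (median 0.69, but -0.76 with spike-in scaling; adjusted p = 0.0419; adjusted p = 0.302 with an estimated correlation), including CRS5, a metallothionein, at 4.19, ENA5, a sodium pump, at 4.16 and AQY1, an aquaporin, at 4.06. Without commercial replicate 1 the list missed the threshold (adjusted p = 0.0517). Meiosis and sporulation markers were higher in 15 of 29 cases and lower in 5 (median 0.58, 1.36 as deposited, 1.21 with median centring, 1.33 without the dimmest 25% of probe sets and 0.18 with the offset of 50, but -0.29 with spike-in scaling; adjusted p = 0.0329; adjusted p = 0.0959 with an estimated correlation), with IME1, the regulator of meiotic entry, at 4.26 and SPO20 at least 4.10-fold higher. The call was lost with the floor raised to background (median 0.02, adjusted p = 0.0865).

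Histone and replication genes were lower in 23 of 25 cases and higher in 2 (median -1.60, adjusted p = 7.05e-05), including RFA3 at -3.76 and RNR1, ribonucleotide reductase, at -3.44. Purine synthesis genes were lower in 16 of 17 cases and higher in 1 (median -1.59, adjusted p = 0.000163), including IMD4 at -3.21 and GUA1 at -2.61. Amino acid synthesis genes were lower in 47 of 58 cases and higher in 6 (median -1.29, adjusted p = 4.19e-06; adjusted p = 0.0573 with an estimated correlation), including ASN1 at -6.46, HIS1 at -5.00 and LYS12, of lysine synthesis, at -3.43. Cytosolic ribosomal protein genes were lower in 60 of 81 cases and higher in 9 (median -0.93, adjusted p = 4.15e-05; adjusted p = 0.0797 with an estimated correlation): RPL13A changed by -3.02, while RPL21A rose by 4.14 (SE 0.45) and RPP0 by 6.92 (SE 1.89). Ribosome biogenesis genes were lower in 52 of 70 cases and higher in 9 (median -0.83, adjusted p = 0.000168; adjusted p = 0.0797 with an estimated correlation), with NSR1 at -2.79 and NOP1 at -2.74. Mitochondrial ribosomal protein genes were lower in 32 of 56 cases and higher in 6 (median -0.48, adjusted p = 0.0101; adjusted p = 0.0901 with an estimated correlation), with MRPL1 at -2.48.

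Cyclins and mitosis genes were lower in 12 of 18 cases and higher in 1 (median -1.33, adjusted p = 0.0101; adjusted p = 0.0761 with an estimated correlation), with CLN2, CLN1 and CLB1 at background and at least 5.91-fold, 5.76-fold and 5.50-fold lower. Without the dimmest 25% of probe sets the call was lost (median -0.54, adjusted p = 0.0979), and the median was -0.76 as deposited, -0.91 with median centring, -0.74 with the offset of 50 and -0.89 with the floor raised to background. Phosphate response genes were lower in 11 of 14 cases and higher in 3 (median -1.41, adjusted p = 0.0127; adjusted p = 0.101 with an estimated correlation), with the acid phosphatases PHO3 at -6.40 and PHO5 at -4.01. Cell wall genes were lower in 22 of 30 cases and higher in 6 (median -1.95, adjusted p = 0.00219; adjusted p = 0.101 with an estimated correlation), with EGT2 at -6.06, SUN4 at -5.84 and CRH1, a chitin-glucan linking enzyme, at -4.81.

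The other 14 lists did not pass in this comparison. Higher and lower members numbered 10 and 5 of 19 for trehalose and glycogen (adjusted p = 0.192), 13 and 8 of 22 for oxidative defence (0.211), 5 and 6 of 13 for glycerol and osmotic genes (0.868), and 5 and 6 of 21 for glycolysis (0.715). They numbered 8 and 4 of 18 for the TCA cycle (0.211), 20 and 12 of 35 for oxidative phosphorylation (0.144) and 8 and 5 of 15 for hexose transport (0.587). RNA polymerases I and III gave 6 and 16 of 24 (0.06), the proteasome 11 and 8 of 34 (0.623), and ergosterol 6 and 14 of 23 (0.0703). Thiamine, biotin and pyridoxine gave 10 and 4 of 16 (0.06), iron, copper and zinc 7 and 14 of 25 (0.303), haploid mating markers 6 and 6 of 21 (0.604) and the BY4743 marker loci 3 and 2 of 5 (0.428). Single genes of these lists moved far: THI4 rose by 5.13, HXT5 by 5.05 and ATH1 by 2.90, and STL1 was at least 75.7-fold higher.

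Of the 19 lists past the threshold in this comparison, 6 passed with an estimated correlation. The ergosterol and thiamine lists, not past it here, passed with the values as deposited (adjusted p = 0.036 and 0.0391) and with median centring (0.0325 and 0.0397). With spike-in scaling the medians of the lower lists fell further, to between -3.65 (cell wall) and -2.11 (mitochondrial ribosomal proteins). Adjusted over the list alone, 30 of 33 lists gave the same counts, and the 3 others differed by at most 1 gene. The 3' minus 5' difference was higher in commercial yeast than in the control by 0.81 for ACT1 and 0.67 for SPT15 (exact two-sided permutation p = 0.1 for each, n = 3 per group), and by 0.61 or more for SRB4, whose 5' probe set lay at background in commercial yeast. How far this difference in RNA quality shaped the calls was not tested.

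The overlap of the 2 dry yeasts was then measured against the shared control. SIP18, SSA3, SFC1, CRC1, POX1 and HSP26 were higher in both, and ASN1, HIS1, SUN4, RPL13A, NOP1 and IMD4 lower in both. Past the threshold in both comparisons with the control were 2195 probe sets that rose in both and 2089 that fell in both, where independent lists of the same lengths would share 1192 and 1134. Another 884 went opposite ways, among them IMA1, PRM8 and AI1, where independent lists would give 2331. A further 1253 passed in dried BY4743 alone and 1559 in commercial yeast alone, which does not show that the others differ. Tested directly, 587 of the 2195 shared rises were higher in commercial than in dried yeast, 740 were lower and 868 did not pass. Of the 2089 shared falls, 865 were higher, 526 lower and 698 did not pass. Across probe sets, which are not independent replicates, the log2 changes correlated at Pearson's r of 0.607 and Spearman's rho of 0.577. In 20 simulations of unchanged groups against the same controls these were 0.505 and 0.454, and the counts shared were 0 higher and on average 0.05 lower. Unchanged groups gave almost no calls at all, on average 0.15 in dried BY4743 alone and 0.1 in commercial yeast alone. The simulated counts therefore do not tell how many calls 2 unrelated responses would share. The simulated correlations are no baseline for 0.607 and 0.577 either. Simulated groups held noise alone, and noise of the shared controls correlates the changes whatever its size. The covariance was 1.79 against 0.0468 simulated, a difference of 1.74. The 3 control arrays were not divided between the 2 comparisons, so part of the excess over independent lists may come from the shared controls. By the covariance, scatter between the control arrays accounts for little of the common change (0.0468 of 1.79). A deviation common to all 3 control arrays is not part of that value. With spike-in scaling the shared rises numbered 490 and the opposite changes 497.

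**Figure D4:**
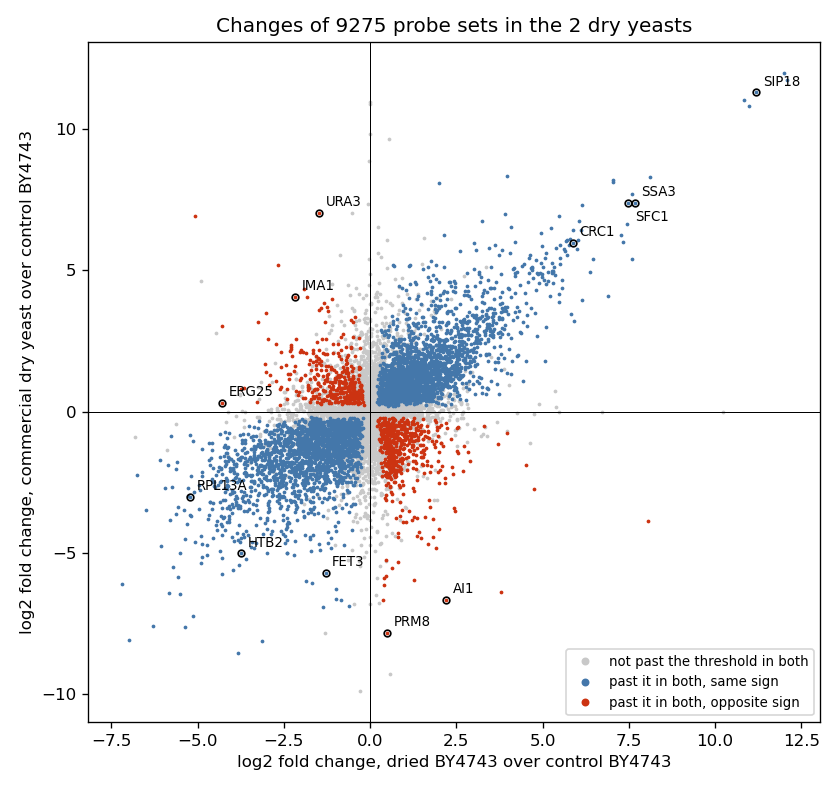
Fitted log2 fold change of 9275 probe sets in dried BY4743 (horizontal axis) and in commercial yeast (vertical axis), each over control BY4743; blue points passed the threshold in both with the same sign, red points in both with opposite signs, grey points not in both. Circled genes are named; fitted values of genes at background in a group, such as SIP18 and URA3, are not measured folds. The 2195 shared rises and 2089 shared falls outnumber the 884 opposite changes; with spike-in scaling there were 490 shared rises and 497 opposite changes.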

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

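Chosen only after the results were seen were the test on the other control transcripts, both spike-in tests, the chromosome-end test and the test of signal over background; the remaining tests were set beforehand.

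Dried BY4743 arrays gave more signal on several ribosomal RNA control probe sets, which no comparison used. The 18S probe sets a, b and c averaged 225, 140 and 85.0 in dried BY4743, against 77.5, 63.7 and 32.6 in the control, while the 18S probe set e went from 71.1 in the control to 43.7 and the 25S probe set d, at 37.8 in the control, was slightly lower in dried BY4743. Probe set a of 18S scattered widely in dried BY4743, at 126, 172 and 378 on its arrays. The 25S probe set a averaged 2369 in dried BY4743 and 3349 in commercial yeast, against 989 in the control. The control probe set of URA3 averaged 681 in commercial yeast. A set of 42 probe sets that name no single gene lay at background on all BY4743 arrays and above it, by at least 1 on the log2 scale, on all commercial arrays.

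The opposite set is the first pattern weighed: 35 probe sets, 25 of them naming a gene, lay above background in both BY4743 groups and at background in commercial yeast, among them PRM8, PDS5, RCK2, BAP3 and PRY2. Among the 21 genes whose brightest probe set was in this set there were 0 neighbouring pairs, where matched random gene sets had 0.0767 on average. Genes with a brighter probe set outside the set were left out. Multi-gene stretches missing from the commercial strain predicted more pairs than that, and no pair was seen. Neighbours that miss the margin are not counted, as with AI2 and AI3 near AI1, so the test cannot exclude such stretches. Divergence or loss of single genes stays open too. Of these 21 genes 4 lay within 10 genes of a chromosome end (AIF1, CHA1, UIP3 and PHR1), against 0.854 in random sets (permutation p = 0.007), which is consistent with gene content near chromosome ends that differs between strains, as a hypothesis for those genes. Members among the dimmest of 3 equal parts of BY4743 signal made up 60% (95% interval 42.1% to 76.1%), which alone decided nothing, but the other 1597 probe sets in that part changed by a median of only 0.23 (SE 0.16) in log2 signal over background, and by -0.25 (SE 0.15) as deposited, which argues against a common loss of 1 or more on the commercial arrays as the whole cause. Culture and drying of the commercial yeast differ too, and were not tested.

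The second pattern is the ACT1 difference between 3' and 5' control probe sets, 1.80 higher in dried BY4743 than in the control. General 3' shortening of the RNA would have raised the other control transcripts too. They rose by 0.316 for SPT15 (SE 0.0813) and 0.274 for SRB4 (SE 0.165), far below ACT1. Those values argue against a general shortening as large as the ACT1 rise, but a smaller one stays open. Commercial yeast lay above the control by 0.81 for ACT1, 0.67 for SPT15 and 0.61 or more for SRB4. There the other transcripts rose nearly as much as ACT1, so general 3' shortening stays open for commercial yeast. For dried BY4743 against the control, loss of long transcripts by fragmentation predicted a negative correlation of gene length and log2 change. Spearman's rho was 0.0454 over 5637 genes (95% interval 0.0193 to 0.0714). The ACT1 probe sets lay near the highest signals of the control arrays, with normalized means of 4555 (3') and 5889 (5'), so saturation there could have changed the difference; this was not tested. A change particular to the ACT1 messenger in the dried cells also stays open, untested.

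The last pattern is the spike-in controls, which averaged 1.65 (log2) higher on the commercial than on the control arrays, a 3.14-fold difference seen in 9 of 9 probe sets, and 1.24 higher than on the dried BY4743 arrays. A single scaling factor, or a lower total messenger signal in commercial cells acting through such a factor, would shift all 9 alike. Their shifts had an SD of 0.661 against a mean SE of 0.205, which argues against either as the whole cause. A part played by either, and a hybridisation batch that holds the commercial arrays, stay open, since no dates were given. The 9 shifts ran from 0.742 to 2.81, so 1 factor per array does not describe them. Results with spike-in scaling therefore show how far a call rests on the scaling, and are not a measure of transcript per cell. Which direction the many small changes took per cell was not decided.

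Splits of the 6 arrays into 3 and 3 were too few, at 10 per comparison, for a share under 0.05. The real splits gave 6421, 6170 and 6727 probe sets past the threshold for dried against control BY4743, commercial against dried and commercial against control, each the only 1 of its 10 splits with as many; the highest of the other splits gave 0, 0 and 1.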

How the results depend on the processing

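The spike-in scaling, the floor at background and the restriction to probe sets without shared probes were chosen after seeing the data; the other settings were planned. Counts of probe sets past the threshold stayed within 1.5 times the reported ones under the deposited scale, median centring, the dim filter, the offset, the 6-array fits, eBayes with trend and robust, array weights and both later filters. A 2-fold minimum gave 2019 higher and 2032 lower, 1786 and 1750, and 2095 and 2237 in the order of the comparisons, and 1183, 1154 and 193 for shared rises, shared falls and opposite changes. Spike-in scaling gave 1767 higher in the first comparison, 819 higher and 5387 lower in the second, 814 and 6070 in the third, and 490 shared rises and 497 opposite changes; it lowers the median of all probe sets by construction. Replicate numbers did not pair the arrays (correlation of same-numbered deviations -0.0401 to 0.0432): as a replicate block they gave 3315 and 3015, 2974 and 3041, and 3241 and 3377 probe sets, and 2154, 2047 and 840 shared. With the block the second comparison called 5 lists higher and 1 lower, in place of 9 and 2, with camera adjusted p of 0.0516 to 0.0523 for the lists lost. Those were glycolysis, hexose transport, maltose and sucrose, purines, and iron, copper and zinc, and no other list call changed.

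Lists past the threshold numbered 3 higher and 5 lower with an estimated correlation in the first comparison, 3 and 1 in the second and 4 and 2 in the third. Fry, which asks whether genes move on balance and not against other genes, called 13 and 16, 21 and 7, and 17 and 12. In the second comparison the lists lower fell from 2 to 1 without the dimmest 25%, with the floor at background and without shared probes, and the lists higher rose from 9 to 14 with the offset, to 12 with the values as deposited and with median centring and to 13 with spike-in scaling. The lists higher fell to 6 without the dimmest 25% and to 7 without shared probes. The cause of these shifts was not tested. Camera compares a list with the other genes, whose median was -1.10 with spike-in scaling. Lists that joined as higher there had negative medians, from -0.03 (mitochondrially encoded) to -0.71 (glycerol), so their members were mostly not raised.

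Leaving out each array in turn gave 3123 to 3255 higher and 2885 to 2939 lower in the first comparison, 2825 to 2906 and 2895 to 3016 in the second, 3117 to 3178 and 3261 to 3338 in the third, and 2069 to 2129, 1957 to 2077 and 728 to 868 shared. Lists ranged over 5 to 5 higher and 9 to 10 lower, 8 to 11 and 1 to 2, and 10 to 10 and 9 to 9. The RNA quality differences ranged over 1.64 to 1.90, -1.08 to -0.93 and 0.66 to 0.92 for ACT1, 0.26 to 0.37, 0.31 to 0.42 and 0.63 to 0.74 for SPT15, and 0.12 to 0.36 for SRB4 in the first comparison; in the others SRB4 was only bounded.

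Over 214 results of genes named in the text, 3 reversed, all with spike-in scaling, which shifts every gene down by construction. In commercial against dried BY4743, GRE1 went from 0.68 to -0.23 and LYS2 from 1.05 to -0.23, where neither passed. In commercial against control BY4743, MET17 went from 0.68 to -0.97 and passed in the other direction (limma, Benjamini-Hochberg adjusted p = 0.0162). That scaling took the call from 9 further results, and the floor at background took it from 6; no other single setting took it from more than 3. Leaving out arrays took it in 10 of 1284 fits. Shared responses were not run with the offset, the dim filter, trend, weights or 6 arrays, nor lists with trend.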

Other observations

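Mitochondrial intron reading frames, which no fixed list held and which were chosen after their values were seen, differed between groups, in which strain, culture and drying change together. AI1, AI2 and AI3, reading frames inside introns of COX1, read 473 ± 28.6, 119 ± 18.3 and 105 ± 6.04 in dried BY4743 (n = 3), 102 ± 15.2, 40.9 ± 19.6 and, at background, 28.1 ± 1.72 in the control, and lay at background in commercial yeast, at least 12.7-fold, 3.19-fold and 2.83-fold lower. The fitted changes, which count commercial signals under background, gave limma adjusted p = 3.88e-09, 8.63e-06 and 2.82e-09, and these do not test the bounds. SCEI, the endonuclease of the ribosomal RNA intron, read 76.0 ± 15.4 in dried BY4743 and lay at background in commercial yeast, at least 2.02-fold lower, but also in the control (26.0 ± 9.27), so AI3 and SCEI do not set BY4743 as a strain apart. AI2 does not do so clearly either, as commercial yeast was only at least 1.005-fold below the control. AI5_ALPHA and AI5_BETA, of later COX1 introns, were above background in commercial yeast at 103 ± 14.0 and 52.8 ± 16.7. Both were lower there than in dried BY4743, by log2 changes of -0.75 and -1.12 (limma adjusted p = 0.0154 and 0.00536). Between commercial and control yeast AI5_ALPHA did not pass the threshold (limma adjusted p = 0.436). BI4, in an intron of COB, read 193 ± 38.8 by 1 probe set in commercial yeast alone, at least 3.74-fold above dried BY4743, whereas by another it read 49.1 ± 10.5 in dried and 78.2 ± 8.46 in commercial yeast. COX2 lay at background in both BY4743 groups and read 358 ± 17.1 in commercial yeast.

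Probe sets at background on all BY4743 arrays and above it on all commercial arrays numbered 62, of which 20 named a gene; the examples here were chosen after their values were seen. Besides SUC2 and URA3 they included DAL1, allantoinase, at 223 in commercial yeast, JLP1, a sulfonate dioxygenase, at 422, CDA2, a chitin deacetylase, at 121, and COS12, of a family near chromosome ends, at 129. Of those 20 genes, several rest on probe sets with shared probes, among them YAR068W.

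Control arrays scattered widely for some abundant transcripts, also chosen after their values were seen: ADH1 read 1066 ± 1135, PGK1 729 ± 561, RPP0 152 ± 131 and CCW12 131 ± 113 in the control (n = 3), whereas ADH1 read 5559 ± 60.6 in dried and 6016 ± 19.8 in commercial yeast. Whether signals near saturation were involved was not tested. On the 25S control probe set e, the 3 dried BY4743 arrays read 2788, 4036 and 139, and the control averaged 189.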
